A study of Homo sapiens with 3 samples.

How the data were processed

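The 3 replicate arrays of the HT1080 cell line, which form 1 group, were analysed. Per the labels' protocols, total RNA was extracted with a column kit from confluent cells grown at 37 °C in 5% CO2, and biotinylated cRNA was prepared for Illumina arrays. The authors deposited a table of probe intensities that were not normalized, per the file headers, with a detection p-value beside each. The detection p-values as deposited fall with the intensity and move in steps of 1 in 759, as a rank among negative controls of the same array would. How they were computed is not given in the sources used here. The authors also deposited a table of log2 values for 48801 of the 48803 probes. From the values, it holds quantile-normalized intensities minus a constant of 98.7, on the log2 scale. Each of its columns ranks the probes as that array's intensities do (Spearman's rho 1.00), which bears out the match of columns to arrays, and its median was 6.00 in each column. Values rebuilt in this way lay within 5.07 intensity units of the deposited ones, and 56.9% lay within 0.01. The scanner software and the authors' own normalization settings are not given in the sources used here.

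Intensities were background corrected, quantile normalized and put on the log2 scale with neqc of limma 3.58.1 (R 4.3.3), which infers the background from the detection p-values, with an offset of 16. Quantile normalization gives every array the same distribution. It removes any global shift between arrays, and correction near background can make dim probes more variable. Probes differ in affinity, so expression was not ranked across genes by level. A probe was called detected at a detection p-value under 0.01, and a gene when at least 1 of its probes was detected on all 3 arrays. A gene was called not detected on any array only when none of its probes was detected on any. The level of a gene is that of its probe with the highest mean.

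Probes were named through GEO's platform annotation, which can be old, with symbols updated through gene identifiers of the RefSeq annotation of GRCh38.p14. Of 48803 probes, 27576 had 1 gene symbol, 13 had several and were not named, and 21214 had no gene in the annotation used. Named probes were detected on all 3 arrays in 35.2% of cases and the others in 6.74%. Of 635 genes on the lists, 586 were measured, 1 of them matched through an older symbol. Members with no named probe were not analysed here. Positions were not used, except for the order of genes along chromosomes.

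Before the data were examined, the gene lists, the tests, the alternatives and the rule for naming genes were fixed. By that rule, in the order written, up to 6 detected and up to 4 undetected genes of each list, every gene of a list with at most 12 members, IDH1, NRAS and the 10 genes with the widest replicate span among detected genes could be named. Shares carry exact (Clopper-Pearson) 95% binomial intervals, which treat genes as independent and cover counting error only. Lists were compared with all other named genes by Fisher's exact test, 2-sided, with Benjamini-Hochberg adjustment over 27 lists. Replicate spread was compared, in a resampling test, with 10000 random lists drawn with replacement from 20 bins of mean level, using lists with at least 8 detected genes. There was 1 group, so no test between groups and no paired analysis could be made.

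The scripts were tested on simulated data. With 90% of a list's members detected, 98.8% of 80 simulated lists were called among 18665 genes. With 10% detected, 58.8% of 80 lists were called, so short lists with low shares can be missed. Of 380 lists with the share of other genes, 1.05% were called. In the spread test, over 7858 genes, 80% of 20 lists with an SD raised 2 times were called, and 1.54% of 65 unchanged lists. Alternatives were detection thresholds of 0.05 and 0.002, detection on at least 2 of 3 arrays, each replicate left out, all probes of a gene or genes with 1 probe only, other normalizations, the deposited log2 values, and other filters on dim probes. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.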

Results

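Total RNA from HT1080 cells, an established human fibrosarcoma cell line, was hybridised as biotin-labelled cRNA to Illumina expression BeadArrays. The series held 1 group of 3 arrays, labelled replicates 1, 2 and 3, from cells grown to confluence in medium with 4 g of glucose per litre and 10% fetal bovine serum. No treated or contrasting samples were part of the design, so the data address which genes this cell line expressed above background under these conditions, and how closely the replicates agreed. The labels do not say whether the replicates were separate cultures, so the SD over the 3 arrays may be partly technical. Each array gave an intensity for 48803 probes, and the median intensities were 166.1, 152 and 170.5 in replicates 1, 2 and 3. The number of arrays limits the precision of each level, and levels below are means ± SD of normalized log2 intensity over n = 3 arrays.

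HT1080 cells expressed 7860 of the 18665 named genes (42.1%) above background on all 3 arrays. A further 9793 genes (52.5%) were not detected on any array, and 1012 were detected on some arrays only. At the level of probes, 11837, 12024 and 12261 were detected in replicates 1, 2 and 3 at a detection p-value under 0.01, and 11128 probes (22.8%) were detected on all 3. The dimmest detected probe lay at a log2 level of 6.66, 6.60 and 6.53 in replicates 1, 2 and 3. A gene that was not detected may still be expressed below this limit, or be read by a probe that responds poorly. Of the 127 probes for ribosomal protein, proteasome and tricarboxylic acid cycle genes, which nearly all cells express, 13 (10.2%) were detected on no array. Of the 5911 genes with more than 1 probe, 1753 (29.7%) had a probe detected on all 3 arrays and another detected on none. Among the listed genes named below, 20 of 109 detected genes had such a discordant probe, among them TIMP2, ITGB1, EGFR, LAMA1, PCNA and HRAS.

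Across the 11128 probes detected on all arrays, Pearson's r was 0.989 between replicates 1 and 2, 0.990 between replicates 1 and 3, and 0.993 between replicates 2 and 3. These correlations are across probes, which are not independent replicates. The median SD over the 3 arrays was 0.13 on the log2 scale and its 90th percentile was 0.28. Of these probes, 43 (0.386%) spanned more than 2-fold between arrays. That count was 1 without background correction, 8 in the deposited log2 values, 82 with median scaling, 219 with a detection filter of 0.05 and 1805 with no filter. Replicate 1 lay farthest from the others for 23 of the 43, replicate 2 for 14 and replicate 3 for 6. Among named genes, the widest spans were 1.34 on the log2 scale for CDIPT, which encodes phosphatidylinositol synthase, 1.29 for the actin-linked adaptor CD2AP and 1.22 for the cytokine LIF. The count of probes over 2-fold was 7 without replicate 1, 19 without replicate 2 and 27 without replicate 3. Spans over 2 arrays tend to be smaller than spans over 3, so these counts cannot be set directly against the 43.

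**Figure D1:**
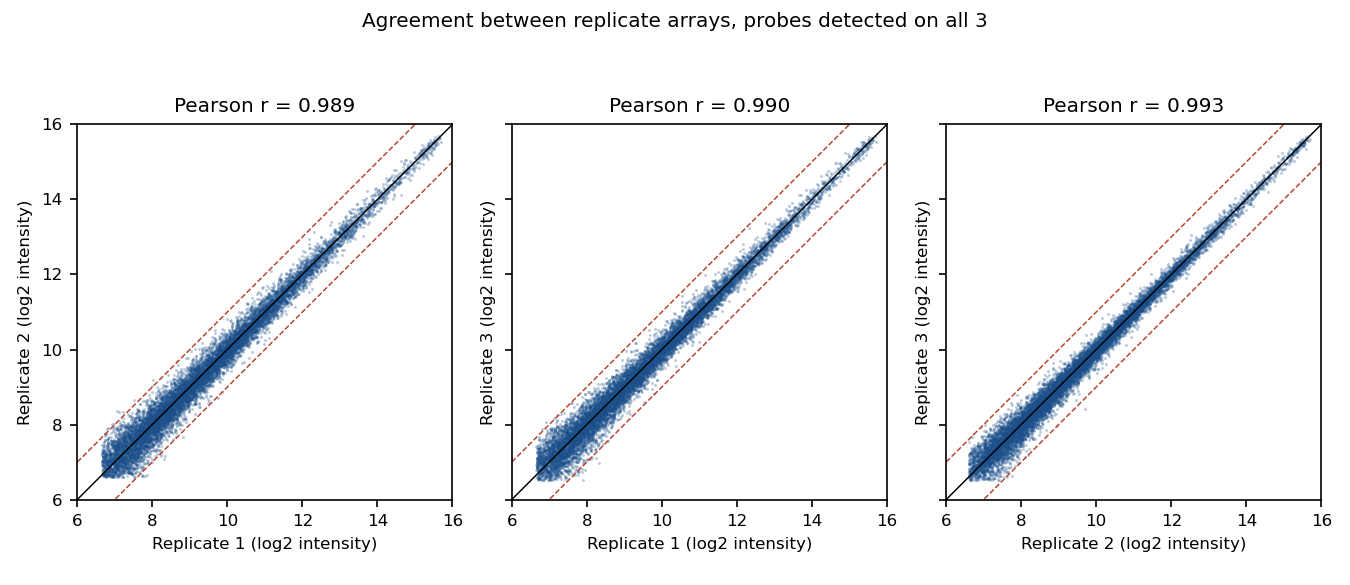
Normalized log2 intensity of each probe detected on all 3 arrays, for each pair of replicates; the solid line marks equality and the dashed lines a 2-fold difference. Points lie along the line of equality in each panel, with Pearson's r of 0.989, 0.990 and 0.993, and scatter most near the lower end.

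To describe which groups of genes were detected above background, 27 gene lists were used, and the detected share of each was tested against all other named genes. Of these, 9 lists had a higher share and 6 a lower share than other genes at an adjusted p below 0.05 (Fisher's exact test, 2-sided, Benjamini-Hochberg over 27 lists), and 12 did not pass the test. Genes are not independent replicates, so these tests describe the 3 arrays and not a population of cultures. In what follows, adjusted exact p refers to this test. When a replicate is left out, detection is required on the 2 remaining arrays in place of 3. A list's share can then only stay or rise, so a rise alone does not show dependence on that replicate.

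**Figure D2:**
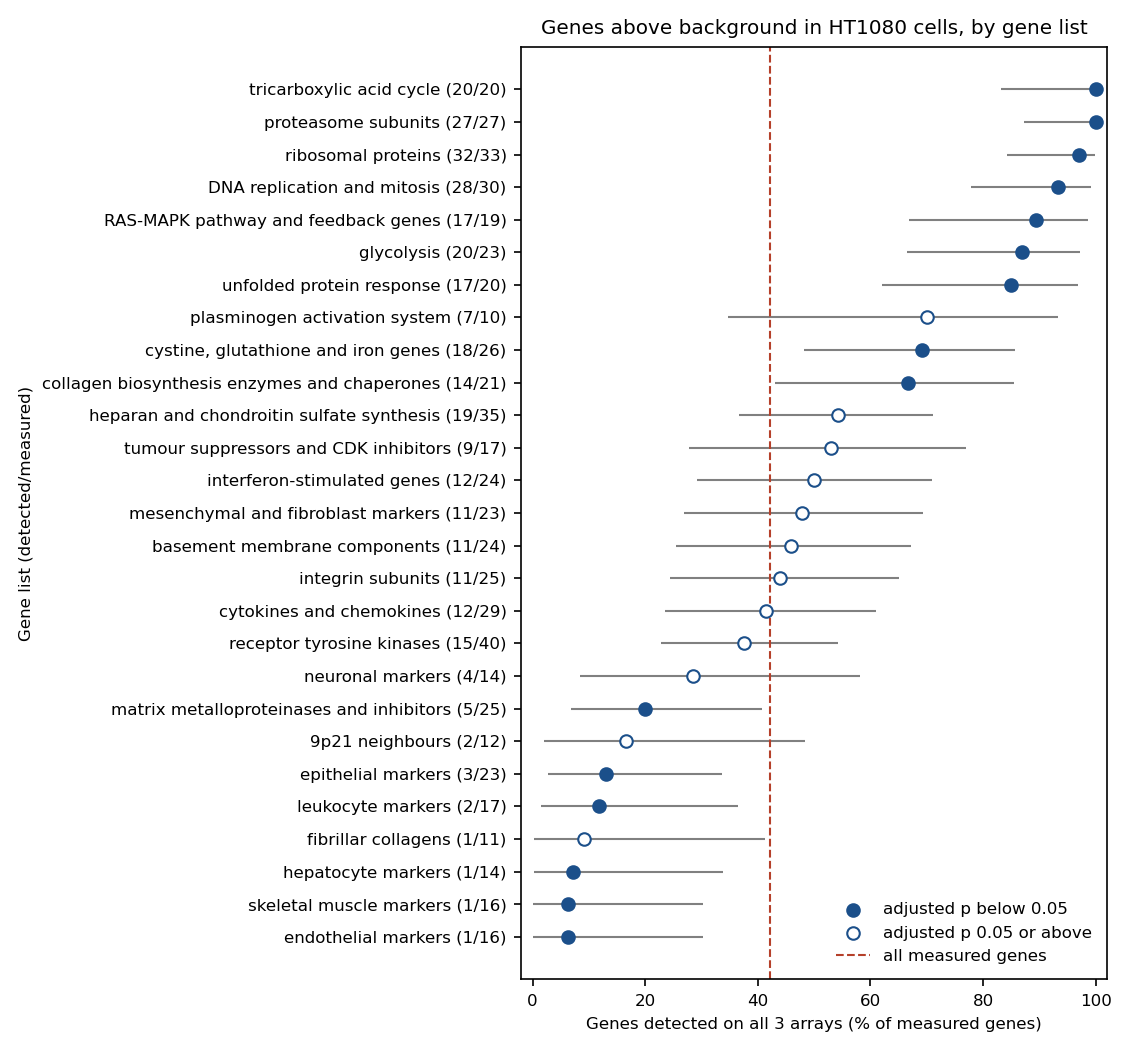
Share of measured genes detected on all 3 arrays in each of 27 gene lists (points) with exact 95% binomial intervals (bars); filled points passed the test against other genes, and the dashed line marks the 42.1% of all named genes. Lists of general cell machinery lie at the upper end and most markers of other cell types lie below 30%.

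Mesenchymal markers were detected more often than epithelial ones, though keratins of simple epithelia were among the genes detected. The intermediate filament gene VIM (15.27 ± 0.09), the N-cadherin gene CDH2 (12.25 ± 0.02), and the transcription factor genes TWIST1 (9.32 ± 0.08) and SNAI2 (8.97 ± 0.10) were detected on every array. So were PDGFRB (7.57 ± 0.28), a platelet-derived growth factor receptor, and S100A4 (7.73 ± 0.11). The fibronectin gene FN1 (5.82 ± 0.58, 3 probes), THY1 (4.92 ± 0.20, 1 probe), ZEB1 (5.62 ± 0.05, 1 probe) and ZEB2 (6.18 ± 0.18, 2 probes) were not detected on any array. In all, 11 of 23 measured mesenchymal and fibroblast markers were detected (47.8%, exact 95% interval 26.8 to 69.4%), a share that did not pass the test against other genes (adjusted exact p = 0.758). Only 3 of 23 epithelial markers were detected (13.0%, adjusted exact p = 0.0132): KRT8 (10.23 ± 0.11), KRT18 (13.06 ± 0.17) and KRT7 (7.69 ± 0.24). The E-cadherin gene CDH1 (5.10 ± 0.43), KRT19 (5.08 ± 0.16), KRT5 (4.97 ± 0.12) and KRT14 (4.88 ± 0.09) were not. The mesenchymal share exceeded the epithelial share by 34.8 percentage points (Fisher's exact test, 2-sided, odds ratio 6.11, p = 0.0230). Requiring all probes of a gene to be detected reduced the difference to 21.7 points (Fisher's exact test, p = 0.165), and p ran from 0.0106 to 0.165 over the alternatives.

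Markers of other cell types that a culture could hold were mostly not detected. Detection on some arrays only was seen for 2 endothelial markers, 1 leukocyte marker, 1 skeletal muscle marker and 1 hepatocyte marker, which are not counted as detected below. One of 16 endothelial markers was detected (6.25%, adjusted exact p = 0.0110), the receptor gene TIE1 (7.71 ± 0.19), whereas CDH5, KDR, VWF and TEK were not. Of 17 leukocyte markers, 2 were detected (11.8%, adjusted exact p = 0.0253), namely the integrin gene ITGB2 (8.94 ± 0.12) and CSF1R (8.43 ± 0.15), the receptor for macrophage colony-stimulating factor. PTPRC (5.15 ± 0.05), the pan-leukocyte antigen CD45, was not detected, nor were CD3E, CD14 and SPI1. Among 16 skeletal muscle markers the satellite cell factor PAX7 (8.93 ± 0.26) was the one detected (6.25%, adjusted exact p = 0.0110), through 1 of its 2 probes, and DES, MYOD1, MYOG and MYF5 were not. The muscle share was 12.5% without replicate 2 (adjusted exact p = 0.0382) and 0% when all probes of a gene were required (adjusted exact p = 0.0161). Of 14 hepatocyte markers, the fibrinogen gene FGA (7.94 ± 0.23) was detected, with at least 1 of its 5 probes detected on no array, and ALB, APOA1, TTR and SERPINA1 were not (7.14%, adjusted exact p = 0.0156). The hepatocyte share was 0% when all probes of a gene were required (adjusted exact p = 0.0226). The share of the 14 neuronal markers did not pass the test (28.6%, interval 8.39 to 58.1%, adjusted exact p = 0.566), nor when all probes of a gene were required (14.3%, adjusted exact p = 0.355). The 4 detected were TUBB3 (13.13 ± 0.14), SNAP25 (8.35 ± 0.07), GAD1 (8.29 ± 0.04) and NEFL (8.22 ± 0.20), while SYP, MAP2, SYT1 and SLC17A7 were not. The endothelial and muscle calls ended at a detection threshold of 0.05, with 25.0% of each list detected (adjusted exact p = 0.132 for both), and the leukocyte call at a threshold of 0.002 (adjusted exact p = 0.0698). The epithelial, endothelial and leukocyte calls also ended when all probes of a gene were required. When only genes with 1 probe were used, the epithelial, endothelial, leukocyte, muscle and hepatocyte lists each lost their call, with adjusted exact p from 0.0508 to 0.388. Over all alternatives the adjusted exact p ran from 0.00733 to 0.136 for epithelial, 0.00537 to 0.132 for endothelial, 0.00831 to 0.388 for leukocyte, 0.00550 to 0.132 for muscle and 0.0136 to 0.0508 for hepatocyte markers.

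Among extracellular matrix genes, both chains of the ubiquitous type IV collagen, COL4A1 (12.43 ± 0.15) and COL4A2 (9.61 ± 0.12), were detected on every array. The laminin genes LAMC1 (12.60 ± 0.01), LAMB1 (9.74 ± 0.07), LAMA5 (10.48 ± 0.03) and LAMA1 (8.57 ± 0.38) were detected as well. NID1 (6.07 ± 0.51), HSPG2 (5.39 ± 0.30), which encodes perlecan, COL4A3 (5.13 ± 0.26) and COL4A4 (4.91 ± 0.21) were not. In total 11 of 24 basement membrane components were detected (45.8%, interval 25.6 to 67.2%, adjusted exact p = 0.875). Of 11 fibrillar collagen genes, COL5A1 (9.15 ± 0.24) alone was detected on all arrays and COL27A1 (6.63 ± 0.19) on 2 of 3. COL1A1 (5.36 ± 0.27), COL1A2 (5.94 ± 0.35), COL3A1 (4.92 ± 0.13) and COL5A2 (5.17 ± 0.12) were not detected on any, nor were COL2A1, COL5A3, COL11A1, COL11A2 and COL24A1. The fibrillar share of 9.09% missed the threshold (interval 0.230 to 41.3%, adjusted exact p = 0.0520). Without replicate 2 it was 18.2% (adjusted exact p = 0.195), and over all alternatives the adjusted exact p ran from 0.0509 to 0.388.

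Enzymes and chaperones of collagen biosynthesis were detected in 14 of 21 cases (66.7%, adjusted exact p = 0.0484). They included the collagen chaperone SERPINH1 (10.77 ± 0.11), the prolyl 4-hydroxylase subunits P4HB (12.71 ± 0.04), P4HA1 (9.38 ± 0.09) and P4HA2 (9.89 ± 0.10), and the lysyl hydroxylases PLOD1 (11.98 ± 0.09) and PLOD2 (13.08 ± 0.21). P4HA3 (5.00 ± 0.05), LOXL2 (5.00 ± 0.16), LOXL4 (5.16 ± 0.10) and PPIB (6.06 ± 0.44), each read by 1 probe, were not detected. This call ended without replicate 1 (adjusted exact p = 0.0810) and without replicate 3 (adjusted exact p = 0.0509), and when genes with 1 probe or all probes of a gene were required. Without replicate 1 or 3 the share of the list itself stayed at 66.7%, while more genes in all were detected. Over all alternatives the adjusted exact p ran from 0.0181 to 0.118.

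The urokinase gene PLAU (14.43 ± 0.11), its receptor PLAUR (11.34 ± 0.21), the tissue activator PLAT (10.94 ± 0.09) and the inhibitor SERPINE2 (13.78 ± 0.10) were detected on every array. The plasminogen-binding partners ANXA2 (15.40 ± 0.04) and S100A10 (14.38 ± 0.08), and the plasminogen receptor gene PLGRKT (10.48 ± 0.14), were also detected. Plasminogen itself, PLG (4.90 ± 0.15), and SERPINF2 (5.23 ± 0.49) were not, and SERPINI1 (6.36 ± 0.37) was detected on 1 array. The share, 7 of 10 (70.0%, interval 34.8 to 93.3%), did not pass the test (adjusted exact p = 0.161), and passed it when all probes of a gene were required (70.0%, adjusted exact p = 0.0377). Of 25 matrix metalloproteinase and inhibitor genes, 5 were detected (20%, adjusted exact p = 0.0484). These were the membrane-bound MMP14 (8.57 ± 0.06) and MMP16 (7.41 ± 0.20), the stromelysin MMP3 (7.71 ± 0.15), and the inhibitors TIMP1 (13.44 ± 0.15) and TIMP2 (12.63 ± 0.12). MMP2 (6.20 ± 0.18), MMP1 (6.34 ± 0.26), MMP9 (5.31 ± 0.03) and RECK (5.92 ± 0.77) were not detected, the first 3 of them each read by 1 probe. The metalloproteinase call was lost without replicate 1 (24.0%, adjusted exact p = 0.114) and at a detection threshold of 0.05 (32.0%, adjusted exact p = 0.157), 0.002 or detection on 2 of 3 arrays, and with both rules on the probes of a gene. Over all alternatives the adjusted exact p ran from 0.0444 to 0.250 for the metalloproteinases and from 0.0377 to 0.331 for the plasminogen system.

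**Figure D3:**
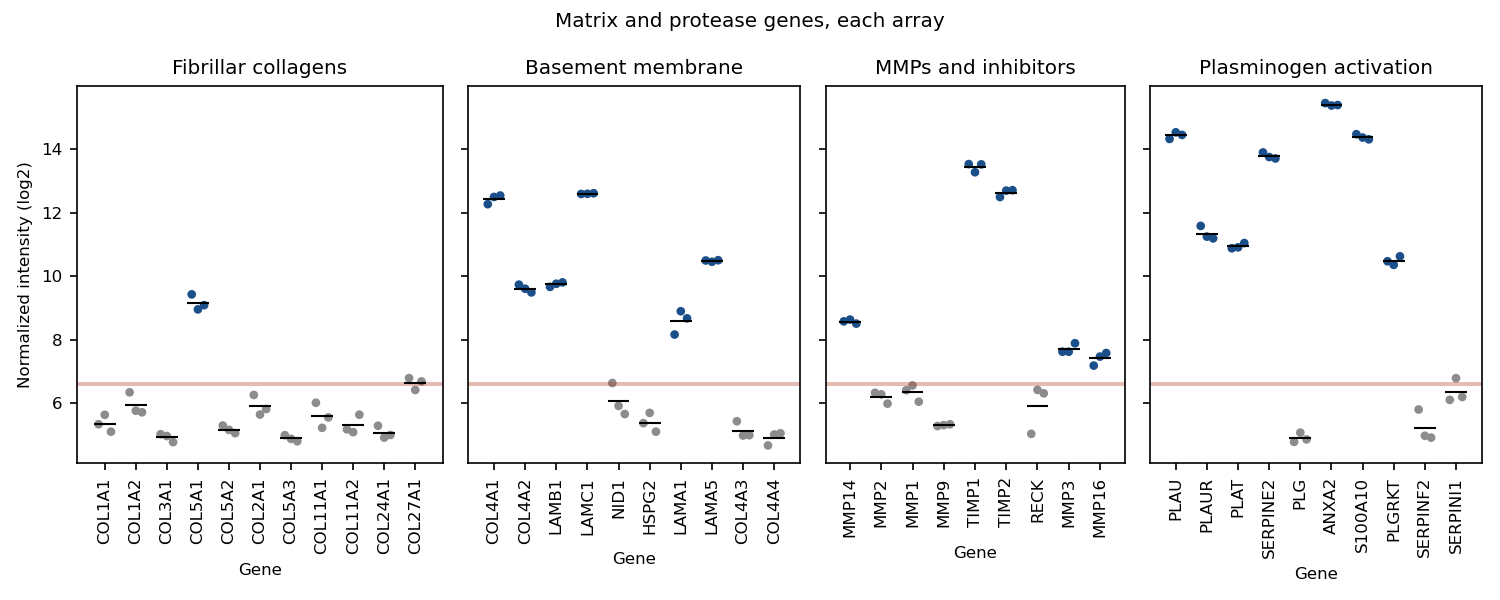
Normalized log2 intensity of the matrix and protease genes allowed by the naming rule, on each array (points) with the mean of the 3 arrays (black line). For the basement membrane and metalloproteinase lists the rule picks some genes by their detection, so these panels do not show the detected shares. Blue genes were detected on all 3 arrays and grey genes were not, and the shaded band spans the dimmest detected probe of the arrays, from 6.53 to 6.66.

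Adhesion and growth factor receptors were detected in part. Of 25 integrin subunits, 11 were detected (44.0%, interval 24.4 to 65.1%, adjusted exact p = 0.875). They included ITGB1 (14.39 ± 0.05), the beta subunit shared by many collagen, laminin and fibronectin receptors, with ITGA5 (12.30 ± 0.12), ITGA3 (13.18 ± 0.19), ITGA2 (11.93 ± 0.07), ITGA6 (9.61 ± 0.15) and ITGAV (9.61 ± 0.43). ITGB3 (5.82 ± 0.31), ITGA1 (5.34 ± 0.24), ITGA7 (5.14 ± 0.20) and ITGA8 (4.81 ± 0.17) were not. The integrin share lay below that of other genes when all probes of a gene were required (28.0%) and at a threshold of 0.05 (44.0%). Among 40 receptor tyrosine kinases, 15 were detected (37.5%, interval 22.7 to 54.2%, adjusted exact p = 0.742), among them AXL (13.08 ± 0.06), EPHA2 (9.83 ± 0.10), ERBB2 (9.49 ± 0.03), EGFR (8.60 ± 0.18) and MET (8.47 ± 0.16). FGFR1 (5.29 ± 0.64), INSR (6.17 ± 0.13), KIT (5.39 ± 0.09) and ERBB3 (5.54 ± 0.12) were not. Without replicate 1 the kinase share was 47.5%, above that of other genes. It was 22.5% when all probes of a gene were required (adjusted exact p = 0.413), a rule that also lowered the number of detected genes.

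The RAS-MAPK pathway was detected almost throughout, at 17 of 19 measured genes (89.5%, adjusted exact p = 1.14e-04). HRAS (10.36 ± 0.08), the kinase genes ARAF (10.08 ± 0.18), MAP2K1 (11.12 ± 0.10), MAP2K2 (11.04 ± 0.10) and MAPK3 (10.29 ± 0.06), and the ERK phosphatase gene DUSP4 (7.40 ± 0.09) were above background on all arrays. The phosphatase gene DUSP6 (5.64 ± 0.18, 2 probes) and the transcription factor gene ETV1 (4.99 ± 0.18) were not. A further 6 members of this list, NRAS among them, had no probe named in the annotation used and were not analysed here.

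In these cells, harvested at confluence, genes of DNA replication and mitosis were detected in 28 of 30 cases (93.3%, adjusted exact p = 4.09e-08). Examples are the proliferation marker MKI67 (7.29 ± 0.07), the replication clamp PCNA (11.81 ± 0.09), the helicase subunit MCM2 (10.71 ± 0.05), the mitotic kinase CDK1 (10.57 ± 0.21), its cyclin CCNB1 (9.34 ± 0.16), and TOP2A (11.73 ± 0.16). CCNE2 (5.17 ± 0.33) and CDC6 (6.15 ± 0.48) were not detected. Of 17 tumour suppressor and CDK inhibitor genes, 9 were detected (52.9%, interval 27.8 to 77.0%, adjusted exact p = 0.595). CDKN1A (13.94 ± 0.07), the p21 inhibitor, CDKN1B (8.38 ± 0.23), CDKN2D (8.41 ± 0.09), RB1 (8.52 ± 0.12), SMAD4 (10.34 ± 0.22) and VHL (9.38 ± 0.04) were detected, whereas NF1 (5.72 ± 0.24), NF2 (6.47 ± 0.11), CDKN1C (5.10 ± 0.06) and APC (5.12 ± 0.43) were not. Among genes with 1 probe this share was 33.3%, below that of other genes. NF1, CDKN1C and APC were each read by 1 probe.

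In the list of genes at and near the 9p21 tumour suppressor locus, 2 of 12 were detected on all arrays (16.7%, interval 2.09 to 48.4%, adjusted exact p = 0.136). KLHL9 (10.92 ± 0.10) and FOCAD (8.67 ± 0.22) were detected. MTAP (5.03 ± 0.08), the enzyme of methionine salvage, and the CDK inhibitor genes CDKN2A (5.56 ± 0.20, 3 probes) and CDKN2B (6.43 ± 0.19, 3 probes) were not detected on any array. DMRTA1, ELAVL2, MLLT3, IFNB1, IFNA1 and IFNA2 were also not detected, and IFNE was detected on 1 array. At a detection threshold of 0.05 the share of this list was 33.3% (adjusted exact p = 0.478).

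General cell machinery was detected at or near completeness. All 27 proteasome subunits (adjusted exact p = 9.50e-10) and all 20 tricarboxylic acid cycle genes (adjusted exact p = 2.05e-07) were detected, with PSMB5 at 12.75 ± 0.05, CS at 12.43 ± 0.05, IDH1 at 10.93 ± 0.15 and IDH2 at 8.20 ± 0.11. Of 33 ribosomal protein genes, 32 were detected (97.0%, adjusted exact p = 4.87e-10), RPL10 (5.20 ± 0.12) being the exception. Probes for ribosomal proteins may also bind transcripts of processed pseudogenes, so single members are uncertain. Glycolysis genes were detected in 20 of 23 cases (87.0%, adjusted exact p = 8.12e-05), including GAPDH (15.26 ± 0.06), LDHA (14.82 ± 0.09), PKM (12.24 ± 0.10) and HK2 (9.21 ± 0.20). The exceptions were HK3, PKLR and LDHC, which are known for expression in blood cells, liver and testis. Unfolded protein response genes were detected in 17 of 20 cases (85.0%, adjusted exact p = 4.63e-04), with the chaperone HSPA5 at 11.63 ± 0.08, XBP1 at 11.03 ± 0.11, ATF4 at 13.94 ± 0.16 and DDIT3 at 8.39 ± 0.16, while EIF2AK3, DNAJC3 and SEL1L were not.

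Genes of cystine uptake, glutathione and iron handling were detected in 18 of 26 cases (69.2%, adjusted exact p = 0.0188). GPX4 (13.03 ± 0.06), the peroxidase that repairs lipid hydroperoxides, ACSL4 (10.49 ± 0.12), the transferrin receptor gene TFRC (14.54 ± 0.04), the ferritin light chain gene FTL (15.48 ± 0.06), SLC3A2 (8.80 ± 0.06) and GCLC (7.44 ± 0.25) were detected. SLC7A11 (6.25 ± 0.26, 1 probe), the cystine transporter subunit that pairs with SLC3A2, was not, nor were SLC40A1, AIFM2 and GPX2. This call was lost when all probes of a gene had to be detected (46.2%, adjusted exact p = 0.231) and among genes with 1 probe (61.5%, adjusted exact p = 0.188), and the adjusted exact p ran from 0.0124 to 0.231 over all alternatives.

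Secreted signals, interferon response genes and glycosaminoglycan enzymes were each detected in part, and none of the 3 lists passed the test. Of 29 cytokine and chemokine genes, 12 were detected (41.4%, interval 23.5 to 61.1%, adjusted exact p = 1), including IL1B (11.27 ± 0.19), VEGFA (10.27 ± 0.06), CXCL8 (10.06 ± 0.08), IL6 (9.07 ± 0.02), IL1A (7.46 ± 0.29) and CCL2 (6.99 ± 0.12). CXCL1, CXCL2, CXCL3 and TGFB1 (5.28 ± 0.27) were not detected. Without replicate 3 the cytokine share was 48.3%, above that of other genes. Of 24 interferon-stimulated genes, 12 were detected (50%, interval 29.1 to 70.9%, adjusted exact p = 0.658), such as IRF9 (9.49 ± 0.14), MX1 (9.14 ± 0.17), ISG15 (8.88 ± 0.29) and IFIT1 (7.75 ± 0.17), while MX2, IRF7, RSAD2 and IFI44L were not. Heparan and chondroitin sulfate synthesis genes were detected in 19 of 35 cases (54.3%, interval 36.6 to 71.2%, adjusted exact p = 0.242). The heparan sulfate polymerase genes EXT1 (10.47 ± 0.13) and EXT2 (10.98 ± 0.10), NDST1 (9.49 ± 0.12), XYLT2 (11.16 ± 0.10), B4GALT7 (10.51 ± 0.13) and CHSY1 (11.07 ± 0.02) were detected, and XYLT1 (5.03 ± 0.13, 4 probes), EXTL1, NDST3 and NDST4 were not.

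Spread between replicates was also compared across gene lists. Of 17 lists with at least 8 detected genes, 0 passed an adjusted p of 0.05 when the median SD of each was set against 10000 random lists matched on mean level, and 2 had an unadjusted p below 0.05. The 32 ribosomal protein genes had a median SD of 0.07 on the log2 scale against 0.09 for matched lists (permutation test, 2-sided, p = 0.0446, adjusted p = 0.379). The 17 unfolded protein response genes had a median SD of 0.16 against 0.11 (permutation test, 2-sided, p = 0.0444, adjusted p = 0.379). The ribosomal list lay at percentile 2.22 of matched lists, at 84.1 without replicate 1, 28.3 without replicate 2, 6.64 without replicate 3 and 39.9 with median scaling. The unfolded protein response list lay at percentile 97.8, at 55.4 without replicate 1, 56.5 without replicate 2, 85.6 without replicate 3 and 68.2 with median scaling.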

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

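Of the 27 gene lists, 14 kept their direction and their side of the threshold under all 8 alternatives, and 13 changed under at least 1. Of 239 genes checked among those named in the text, 190 kept their call, detected on all arrays or not, under all 7 alternatives run for single genes. No alternative was added after the data were seen. No paired analysis was possible because there was only 1 group. The cause of the changes below was not tested, except that using genes with 1 probe only leaves fewer genes in the test and that requiring all probes lowered the detected genes from 7860 to 5869.

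With detection of all probes of a gene required, calls were lost for epithelial (13.0%), endothelial (6.25%) and leukocyte markers (11.8%), whose own shares did not move, and for collagen biosynthesis (52.4%), metalloproteinase (12%) and cystine, glutathione and iron genes (46.2%). The plasminogen system passed the test (70.0%), integrins (28.0%) and cytokines (34.5%) changed side relative to other genes, and mesenchymal against epithelial markers fell short at 21.7 points. With genes of 1 probe only, calls were lost for epithelial (11.8%), endothelial (7.69%), leukocyte (12.5%), muscle and hepatocyte (0% each), collagen biosynthesis (66.7%), metalloproteinase (18.8%) and cystine, glutathione and iron genes (61.5%), and integrins (33.3%), tumour suppressors (33.3%) and cytokines (40.9%) changed side. At a detection p-value under 0.05, endothelial (25.0%), muscle (25.0%) and metalloproteinase genes (32.0%) lost their calls, and integrins (44.0%) and receptor tyrosine kinases (50%) changed side. At 0.002, leukocyte (11.8%) and metalloproteinase genes (16%) lost theirs. With 2 of 3 arrays, metalloproteinases lost theirs (24.0%), and integrins (44.0%), receptor tyrosine kinases (47.5%) and cytokines (48.3%) changed side.

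With each replicate left out in turn, the share was 66.7 to 71.4% for collagen biosynthesis (calls lost without replicate 1 and without replicate 3), 20 to 24.0% for metalloproteinases (call lost without replicate 1), 37.5 to 47.5% for receptor tyrosine kinases and 41.4 to 48.3% for cytokines, and for these last lists the highest value changed side. The fibrillar collagen share ran from 9.09 to 18.2% and the muscle share from 6.25 to 12.5%, both highest without replicate 2. With 2 arrays to pass in place of 3, shares can only stay or rise, so these rises alone do not show dependence on a replicate. The collagen biosynthesis calls were lost at an unchanged share of 66.7%, as more genes in all were detected. The ribosomal spread lay between percentiles 6.64 and 84.1 of matched lists and that of the unfolded protein response between 55.4 and 85.6. Mean r ran from 0.989 to 0.993, the median SD from 0.0918 to 0.123 and the probes spanning over 2-fold from 7 to 27. These SDs and spans are over 2 arrays and tend to be smaller than those over 3, so they do not show better agreement.

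Quantile normalization without background correction gave a mean r of 0.993, a median SD of 0.10 on the log2 scale and 1 probe over 2-fold. Median scaling gave a median SD of 0.16 on the log2 scale and 82 probes, the deposited log2 values gave 8 probes, and a detection filter of 0.05 gave 219. With no filter on dim probes, mean r was 0.985, the median SD 0.17 on the log2 scale and 1805 probes spanned over 2-fold, and whether low signal or the correction near background set that spread was not tested.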

Other observations

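The gene families in this paragraph and in the next 2 were chosen after the data were seen, and so were the test on generally expressed genes in the paragraph on MTAP, the circular shifts and the tests on neighbours with unlike symbols. Germline genes of the cancer-testis class, which are known for expression in testis and in tumours, were detected on all 3 arrays in several families. Of 25 measured symbols of the MAGEA, MAGEB and MAGEC families, 8 were detected, with MAGEB2 at a log2 level of 12.11 ± 0.06 (mean ± SD, n = 3), MAGEA6 at 11.03 ± 0.10, MAGEA12 at 10.01 ± 0.16, MAGEA3 at 9.51 ± 0.09 and MAGEC2 at 9.41 ± 0.14. MAGEA4 (4.94 ± 0.10), MAGEA10 (5.05 ± 0.29) and MAGEC1 (5.18 ± 0.17) were not detected on any array. Of 7 SSX genes, 5 were detected, including SSX1 (10.77 ± 0.16), SSX2 (9.45 ± 0.07) and SSX4 (9.58 ± 0.17), and both measured GAGE genes, GAGE4 (13.29 ± 0.12) and GAGE7 (10.48 ± 0.45), were detected. Many members of these families are near-identical in sequence, so which members were expressed is uncertain.

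Homeobox genes that mark position along the body axis were detected in part of each of 3 clusters. Of 10 HOXB genes 6 were detected, among them HOXB2 (10.33 ± 0.08), HOXB7 (10.17 ± 0.15) and HOXB5 (9.74 ± 0.17), while HOXB13 (4.93 ± 0.01) and HOXB9 (5.67 ± 0.13) were not detected on any array. Of 9 HOXC genes 4 were detected, with HOXC6 at 10.46 ± 0.11 and HOXC8 at 9.07 ± 0.12. In the HOXD cluster 3 of 9 were detected, HOXD11 (8.04 ± 0.25), HOXD12 (7.20 ± 0.33) and HOXD13 (8.36 ± 0.15). The only HOXA gene with a named probe, HOXA2, was not detected.

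Among 97 groups of at least 20 genes that share the letters before the first digit of their symbols, 24 had a higher detected share than other genes and 27 a lower one at an adjusted p below 0.05 (Fisher's exact test, 2-sided, Benjamini-Hochberg over the groups). Symbols of TTTY followed by a digit were left out of the groups by choice. Such groups can hold antisense genes and pseudogenes named after a family. Olfactory receptor symbols were detected on all 3 arrays in 2 of 382 cases (0.524%, exact 95% interval 0.0635 to 1.88%, adjusted exact p = 2.51e-86), hair keratin-associated proteins in 1 of 79 (adjusted exact p = 3.99e-16), taste receptors in 0 of 27 (adjusted exact p = 3.23e-06), UDP-glucuronosyltransferases in 0 of 21 (adjusted exact p = 8.47e-05) and symbols of FGF followed by a digit, which are fibroblast growth factor genes and some antisense genes but not their receptors, in 0 of 24 (adjusted exact p = 1.63e-05). Mitochondrial ribosomal proteins of the large subunit were detected in 48 of 50 cases (adjusted exact p = 7.09e-15) and zinc finger genes in 157 of 448 (35%, adjusted exact p = 0.00559). Genes of a family are not independent, and members that are close copies can share a probe's signal.

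MTAP, CDKN2A and CDKN2B were not detected on any array, and a hypothesis written before the values were seen was that these 9p21 genes are lost or silent in these cells. Of the 7 probes for these genes, 0 were detected on all 3 arrays, as that hypothesis requires. That outcome only restates the lack of detection, and 52.5% of all named genes were not detected on any array. It therefore does not decide for the hypothesis. The lowest detection p-value among the 7 probes was 0.0119, 1 probe was under 0.05 on some array, and the lowest value of the MTAP probe was 0.385. The technical explanation is failed probes: among 44 genes of the ribosomal protein, proteasome and tricarboxylic acid cycle lists with 1 probe each, 0% were not detected, but of all 127 probes for these lists 13 (10.2%) were detected on no array. RPL10 was missed by both its probes and MTAP has 1 probe, so failure of that probe stays open. Expression arrays cannot tell a lost gene from a silent one. In the order of measured genes, FOCAD, HACD4, KLHL9 and IFNA8 were detected on one side of MTAP and CAAP1 on the other. They lay among undetected genes such as MLLT3, DMRTA1 and ELAVL2, and IFNE and TUSC1 were detected on some arrays only. HACD4, IFNA8, CAAP1 and TUSC1 were chosen after their values were seen.

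A hypothesis written before the values were seen was that detected genes are spread evenly over the chromosomes. Taking genes as independent, 5 of chromosomes 1 to 22 and X differed from the others at an adjusted p below 0.05 (Fisher's exact test, 2-sided, Benjamini-Hochberg), from 37.2% detected on chromosome X (adjusted exact p = 0.0266) to 49.0% on chromosome 16 (adjusted exact p = 0.00337). Neighbouring genes were alike, however, so these p-values are too small and that criterion was wrong. In 1000 circular shifts of the states along the gene order, which keep the likeness of neighbours, 371 gave shares at least as uneven (permutation test, p = 0.372), and the lowest adjusted p of a single chromosome was 0.597 (permutation test). The shifts also keep likeness over long stretches of a chromosome, so they cannot tell an uneven spread over chromosomes from such likeness. The test therefore speaks neither for nor against the hypothesis, which stays open.

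Neighbouring genes shared their state, detected on all arrays or not, more often than chance. Of 18542 adjacent pairs of measured genes, 56.9% were in the same state, against a median of 51.3% and a highest value of 52.5% in 1000 permutations within chromosomes. Families of related genes that lie side by side are a candidate source of this. Among 16359 pairs whose symbols differed in the first 3 letters the share was 54.0%, against a highest value of 52.5% in the permutations, and among 16232 pairs that also differed in the letters before the first digit it was 53.8%, against a highest value of 52.6%. Families recognised by these rules may account for part of the excess, and related genes with unlike symbols were not tested.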
